A study of Mus musculus with 12 samples.

How the data were processed

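Total RNA of isolated hepatocytes and mesenchymal cells of mouse liver was amplified and labelled with an Affymetrix 3′ IVT kit and hybridised to 1 array per sample, per the labels' protocols. The deposited table holds log2 expression values for 22626 probe sets on 12 arrays. RMA, which corrects background, normalizes arrays by quantiles and summarises probes on the log2 scale, is named in the submitters' processing notes, and its version, software and probe annotation are not given in the sources used here. Because RMA forces the arrays to a common distribution, differences are relative to the bulk of the probe sets, and a shift of most genes in one direction would be removed. This holds in particular between the populations, whose expression differs in most genes. The values ran from 2.79 to 15.2, and array medians from 7.19 to 7.44. The scan date or batch of the arrays is not given in the sources used here, so no batch was tested.

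Probe sets were named from the platform annotation: 20380 had 1 gene symbol, 691 several and 1555 none. Of the first, 20351 were matched through their Entrez number to the RefSeq gene table and no symbol changed. Probe sets with several symbols or none named no gene. For each of 12393 genes the probe set with the highest mean over the 12 arrays stood for the gene, and 4956 genes had more than 1 probe set. Genes without a probe set of a single symbol, such as Por, were not analysed here. Several P450 and glutathione transferase genes have close paralogs, so a probe set can take signal from a relative. The 3 probe sets of Cyp2b10 gave hepatocyte differences of 5.52, 6.79 and 7.15.

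Groups and replicate numbers came from the labels. Tests were linear models in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend. A gene was tested if it lay above the 40th percentile of the array in at least 3 arrays of the fit, and it passed at a Benjamini-Hochberg adjusted p under 0.05. Phenobarbital was compared with vehicle within each population on its own 6 arrays. The difference of the effects and the difference between the populations in vehicle mice used all 12 arrays. The comparisons, 32 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Lists with at least 4 tested members were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. In camera with an estimated correlation the correlation was computed from the residuals of few arrays. Members were also adjusted over the list alone. Mean differences of a list covered its tested members, while list means of single arrays covered all measured members, tested or not.

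Named genes were the 10 of each sign with the widest difference among genes that passed with non-overlapping groups, or where none passed the 3 of each sign with the smallest p. For each list, up to 4 members that passed or, if none, up to 2 with the widest difference were eligible, and a set of genes tied to phenobarbital response was always named where measured. Members that passed only over their own list, the clock genes and the genes given without single arrays were chosen after their values were seen.

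Hepatocyte RNA in the mesenchymal arrays was described by the mean log2 level of 15 hepatocyte markers, with an exact two-sided permutation test, and by the linear ratio of each mesenchymal array over the hepatocyte mean. Carry-over of Cyp2b10 was compared with hepatocyte genes whose hepatocyte level lay within 1 of it on the log2 scale and that differed by −3 or less between mesenchymal cells and hepatocytes. No pair of arrays had identical values, and the smallest median absolute log2 difference between 2 arrays of a group was 0.107. Deviations from the group means were correlated between samples of the same number to see whether numbers paired samples. For hepatocytes and mesenchymal cells of vehicle mice the correlations were 0.197, 0.175 and 0.149, each highest with its own number. A replicate block was therefore tried as an alternative. The main fits had no block and did not account for this pairing. Between vehicle and phenobarbital samples they ran from −0.276 to 0.143, and between hepatocytes and mesenchymal cells of phenobarbital mice from −0.0316 to 0.0631.

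The fits were tested on simulated data with known differences. With 100 genes changed by 1 and 100 changed by 2 on the log2 scale, 86% and 98% were recovered in the hepatocyte fit, 81% and 97% in the mesenchymal fit, 70% and 94% in the difference of effects and 84% and 99% between populations. Unchanged genes called in these runs were 14, 10, 10 and 10. Noise was drawn independently for each gene, and far more genes were changed than passed in the phenobarbital comparisons. This made the adjusted threshold easier to reach, so these shares are not the power of the phenobarbital fits on the real data. Alternatives changed the filter, the scaling, the probe set rule, the eBayes settings, array weights, the arrays in the fit and each array left out in turn. Tables were handled in Python 3.11.15 with pandas 2.3.3 and plots drawn with matplotlib 3.10.9.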

Results

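Gene expression was measured on Affymetrix 3′ arrays in hepatocytes, the metabolic parenchymal cells of the liver, and in a fraction called mesenchymal cells, both isolated from the livers of male C57BL/6N mice. The mice had received phenobarbital at 50 mg/kg per day in the drinking water for 14 days, or water alone as the vehicle. Phenobarbital is a barbiturate that activates the nuclear receptor CAR in liver and is a standard inducer of drug metabolism. The 12 arrays formed 4 groups of 3: hepatocytes of vehicle mice, hepatocytes of phenobarbital mice, mesenchymal cells of vehicle mice and mesenchymal cells of phenobarbital mice. The labels give each array as a separate sample of its group without stating how many animals stood behind it, so the p-values measure the spread between these samples. Arrays of one group correlated at r between 0.989 and 0.996 over all probe sets, and arrays of different populations at r between 0.731 and 0.783. The number of arrays limits the precision of every value. Values are RMA expression on the log2 scale, differences are log2 differences with their standard error (SE), and each group mean is given with its SD and n = 3.

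The first comparison describes what the isolated populations held in vehicle mice. The mesenchymal fraction was rich in macrophage and sinusoidal endothelial transcripts and poor in hepatocyte transcripts. All 13 measured markers of Kupffer cells, the resident liver macrophages, were higher in mesenchymal cells, by a mean log2 difference of 7.47. They included the complement genes C1qb (8.77, SE 0.24) and C1qa (7.70, SE 0.13) and the scavenger receptor Cd163 (8.54, SE 0.18). All 15 markers of liver sinusoidal endothelium were higher as well, by a mean of 6.19, with Oit3 at 7.20 (SE 0.15), the angiopoietin receptor Tek at 7.21 (SE 0.15) and the hyaluronan receptor Stab2 at 6.25 (SE 0.15). Of the 10 tested markers of stellate cells and fibroblasts, 8 were higher, by a list mean of 2.69, among them Rgs5 (5.30, SE 0.28) and Dcn (4.72, SE 0.27). All 15 hepatocyte markers were lower, by a mean of −3.98, with the transcription factor Hnf4a at −4.36 (SE 0.19) and prothrombin (F2) at −4.91 (SE 0.26). Albumin (Alb) differed by −1.15 (SE 0.26) from a hepatocyte level of 15.04, close to the highest value on these arrays (15.1), where differences are compressed. At the other end, Cd163, Oit3 and Rgs5 had vehicle hepatocyte means of 4.36, 6.08 and 4.91. These lay below the 40th percentile of each vehicle hepatocyte array (6.54 to 6.58). Differences from such low levels are rough and may be too small.

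Other blood and immune cells were also represented in the mesenchymal fraction. Of the 8 dendritic cell markers tested 7 were higher there, among them the MHC class II genes H2-Aa (8.35) and H2-Ab1 (7.60). H2-Ab1 had a vehicle hepatocyte mean of 6.02, below the percentile used to filter genes in each vehicle hepatocyte array (6.54 to 6.58). The difference of H2-Ab1 is therefore rough and may be too small. Of the 10 T and NK cell markers 8 were higher, such as Klrk1 (4.17) and Ccl5 (3.62). Among B cell markers 3 of 4 were higher, and among neutrophil markers 3 of 4 were higher and 1 was lower. For platelet markers 1 was higher and 2 were lower, for cholangiocyte markers 1 was higher and 1 lower, and both tested erythroid markers were lower. Metabolic lists ran the other way: all 16 cholesterol synthesis genes, all 12 bile acid genes, all 10 periportal genes and all 13 lipogenesis genes were lower in mesenchymal cells. The proliferation marker Mki67 was higher in mesenchymal cells by 3.41 (SE 0.21). The receptors Nr1i3 (CAR) and Nr1i2 (PXR) were lower by log2 differences of −4.04 (SE 0.37) and −3.78 (SE 0.15). The vehicle hepatocyte mean of Mki67 (5.24) also lay below the filter percentile of its arrays. So did the vehicle mesenchymal means of Nr1i3 (4.95) and Nr1i2 (5.44), against 6.64 to 6.68 in those arrays. These differences are rough as well and may be too small. In limma with Benjamini-Hochberg adjustment, 7470 of 9031 genes differed, 3793 higher and 3677 lower in mesenchymal cells, and 3818 of them by at least 2-fold. The genes with the highest differences besides those named were Vsig4, Lyz1, Ctss, Clec1b, Adgre4, Cd5l and Fabp7, and those with the lowest were Nat8f2, Nox4, Elovl2, F13b, Hsd3b5, Baat, Bhmt2, Igfbp1, Dpys and Cyp2c23. As sets, 21 of 28 lists passed limma's camera, and none did with an estimated correlation (lowest adjusted p = 0.350). By directional fry, which tests whether the genes of a list move one way and does not compare them with other genes, 28 of 28 passed.

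**Figure D1:**
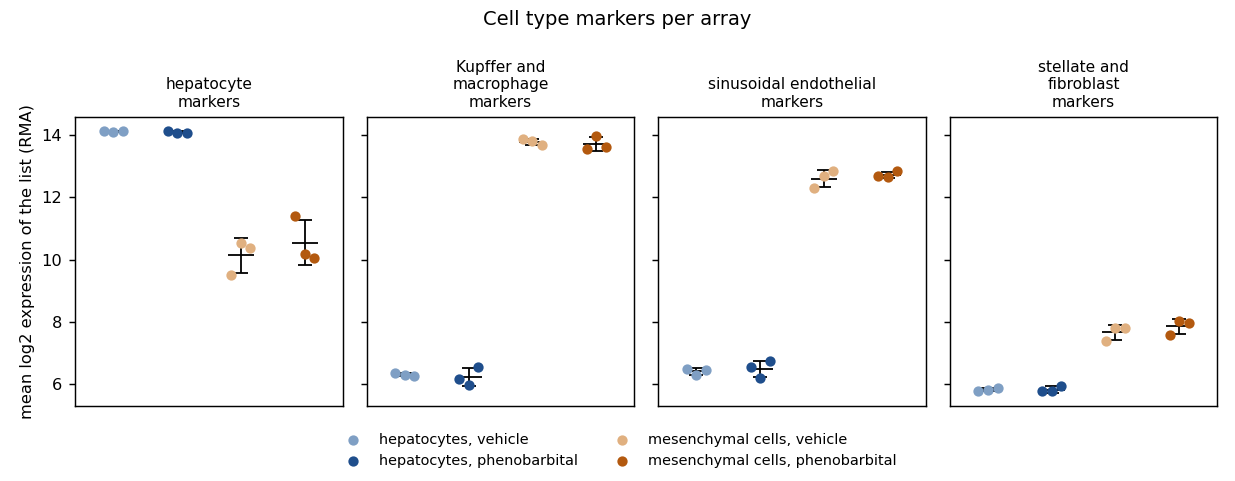
Mean log2 RMA expression of 4 marker lists (vertical axis), 1 point per array, with the group mean (bar) and SD (whiskers, n = 3). Hepatocyte markers averaged 14.1 in hepatocytes of vehicle mice and 10.1 in mesenchymal cells of vehicle mice, and 1 mesenchymal array of phenobarbital mice lay above the other 2.

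The vehicle samples numbered 1 stood apart in both populations in the genes of the circadian clock, a list added after the values were seen. Dbp, a clock output gene, was at 6.21 in that hepatocyte array and at 6.52 in that mesenchymal array. The other hepatocyte vehicle arrays had 11.87 and 11.60, and the phenobarbital hepatocyte arrays lay between 11.89 and 12.15. Arntl, a core clock activator, was at 9.57 and 9.36 in these 2 arrays, against 5.73 and 6.20 in the other hepatocyte vehicle arrays and 7.31 and 6.84 in the other mesenchymal vehicle arrays. In the mesenchymal arrays of phenobarbital mice Dbp lay between 11.65 and 12.15 and Arntl between 6.68 and 6.94.

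**Figure D2:**
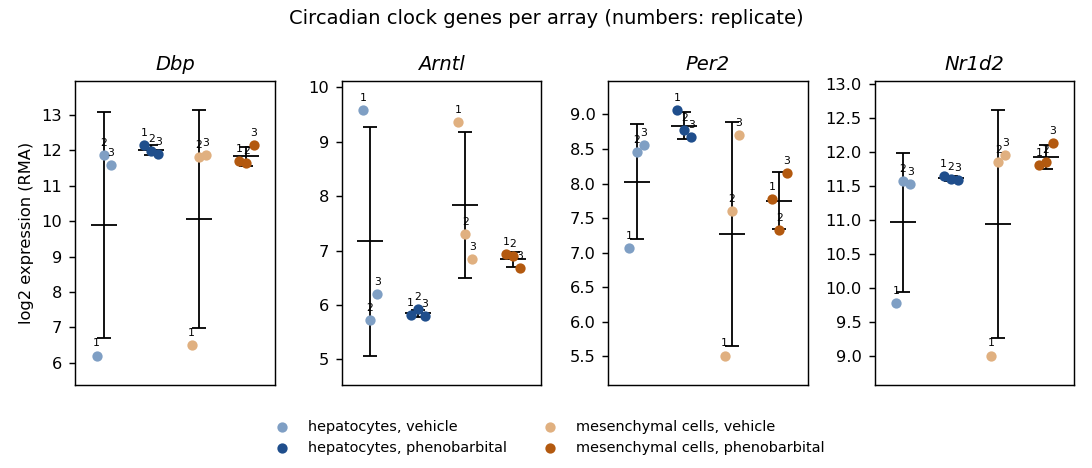
Log2 RMA expression of 4 clock genes (vertical axes) in the 12 arrays, with the replicate number at each point, the group mean (bar) and SD (whiskers, n = 3). Replicate 1 of the vehicle mice has Dbp at 6.21 in hepatocytes and 6.52 in mesenchymal cells.

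The question of how phenobarbital acts on hepatocytes was addressed by comparing the hepatocyte arrays of treated and vehicle mice. Drug-metabolising cytochrome P450 genes rose and a gene of cholesterol synthesis fell. Cyp2b10, the classical CAR target, went from 7.84 ± 0.15 (SD, n = 3) to 13.36 ± 0.69 (SD, n = 3), a log2 difference of 5.52 (SE 0.30) or 45.8-fold, with a limma adjusted p of 0.00123. Cyp2c55 rose from 7.71 ± 0.30 to 11.17 ± 0.70, by 3.46 (SE 0.33), with a limma adjusted p of 0.0213. Cyp2c29 rose by 1.49 (SE 0.12) or 2.81-fold, with a limma adjusted p of 0.00862. Fdft1, which encodes squalene synthase, fell by 0.63 on the log2 scale (SE 0.07), with a limma adjusted p of 0.0486. In each of these 4 genes the 3 treated arrays all lay on one side of the 3 vehicle arrays. These were the genes that passed among 8117 tested, while 680 had an unadjusted p under 0.05, where chance gives 406. The groups did not overlap in 1223 genes (15.1%, where chance gives 10%). Genes are not independent of each other, and neither excess was tested. In mesenchymal cells the share without overlap was 7.70%.

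Leaving out 1 array at a time gave between 1 and 5 genes, and Cyp2b10 passed each time. The number was 1 without vehicle array 2 or treated array 1, 2 without treated array 2, and 5 without treated array 3. Cyp2c55, Cyp2c29 and Fdft1 were lost in 4, 4 and 6 of these 6 fits. Without vehicle array 1, whose clock genes stand apart, the 5 genes were Cyp2b10, Cyp2c29, Cyp2c55, Bcl6 (2.21) and Sbk1 (0.77). With all 12 arrays in 1 fit only Cyp2b10 passed, and with the mean of its probe sets Fdft1 had a difference of −0.26 (limma adjusted p 0.567).

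**Figure D3:**
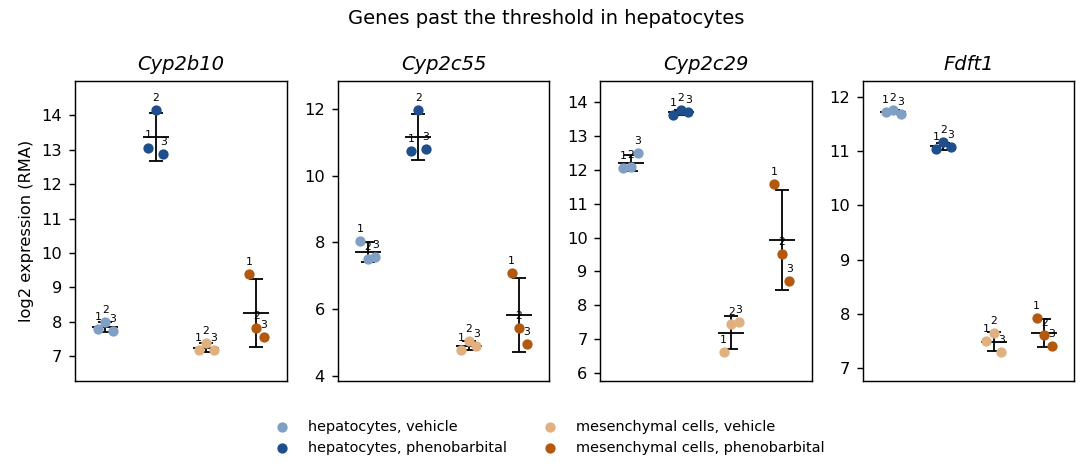
Log2 RMA expression of the 4 genes past the threshold in hepatocytes (vertical axes) in all 12 arrays, with the replicate number at each point, the group mean (bar) and SD (whiskers, n = 3). The treated hepatocyte arrays lie above the vehicle arrays in 3 genes and below them in Fdft1.

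Among the P450 enzymes and partners induced through CAR and PXR, 12 of 15 tested members had positive differences, with a mean of 1.02 and a median of 0.17. 3 of them passed over all genes tested and 7 passed adjusted over the list alone, all higher. Besides Cyp2b10, Cyp2c55 and Cyp2c29 these were Cyp2c54 (1.99, SE 0.29), Cyp2c37 (1.55, SE 0.37), Cyp2c50 (1.10, SE 0.20) and the retinaldehyde dehydrogenase Aldh1a1 (0.31, SE 0.10), which did not pass without vehicle array 1 or 3 or treated array 2 or 3. Genes that passed only over their own list are named here after their values were seen. Cyp3a11, a PXR target, had a difference of 0.07 (SE 0.05) and Alb one of −0.02 (SE 0.04), both from vehicle levels near the top of the scale (14.54 ± 0.04, SD, n = 3, for Cyp3a11), where differences are compressed and the lack of one decides nothing. Alas1, the first enzyme of haem synthesis, had −0.57 (SE 0.26). The receptors Nr1i3 (0.01, SE 0.43) and Nr1i2 (0.21, SE 0.10) did not pass, nor did Gadd45b (0.08, SE 0.25) or the imprinted RNA Meg3 (0.03, SE 0.11). The list was higher by camera (adjusted p = 2.20e-10), a call lost with an estimated correlation (adjusted p = 0.418).

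Conjugation and hydrolysis enzymes were higher as a list by camera (adjusted p = 6.91e-09), with 24 of 27 members positive and a mean of 0.36, a call lost with an estimated correlation (adjusted p = 0.418). Members past the threshold over the list alone were 3, the glutathione transferases Gstt1 (0.52, SE 0.09) and Gstt3 (1.25, SE 0.31) and the sulfotransferase Sult1a1 (0.34, SE 0.06). Gstt3 was lost without vehicle array 1 or 2 or treated array 1 or 2, and 12 members passed without treated array 3. All 9 tested interferon response genes were positive, with a mean of 0.53, and 4 passed over the list alone: Gbp3 (1.30, SE 0.36), Ifit3 (0.77, SE 0.20), Usp18 (0.71, SE 0.21) and Irf7 (0.52, SE 0.16). The list means of single arrays overlapped between the groups, and treated array 2 had the highest, 8.06, against 7.50 and 7.41 in the other treated arrays. Without it the mean was 0.33 and Gbp3 and Ifit3 passed over the list, without vehicle array 2 or 3 none did, and without treated array 3 Usp18 did not. Genes of fatty acid oxidation were positive in 12 of 13 members with a mean of 0.29, and Vnn1 had the highest value (1.05, SE 0.37). Camera called interferon response (adjusted p = 1.51e-05) and fatty acid oxidation (adjusted p = 0.00112) higher. Neither call held with an estimated correlation (adjusted p = 0.418 and 0.582). Without vehicle array 1, whose clock genes stand apart, the mean of the fatty acid oxidation list was 0.09 and its camera call was lost (adjusted p = 0.112), and without treated array 2 they were 0.041 and 0.0669. Without treated array 3 its mean was 0.52 and 5 members passed over the list. The list means of single arrays overlapped for this list too.

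Cholesterol synthesis genes fell together in hepatocytes. All 16 tested members had negative differences, with a mean of −0.52, down to a mean log2 level of 10.48 ± 0.05 (SD, n = 3) in treated mice, and each of the 3 treated arrays lay below each vehicle array in that level. Only Fdft1 passed over all genes, and 14 members passed adjusted over the list alone, all lower. They included Mvd (−1.02, SE 0.15) and Hmgcs1 (−0.80, SE 0.11) of the mevalonate pathway, and Sqle (−0.70, SE 0.10), the squalene epoxidase. Srebf2, the transcription factor that controls the pathway, and Sc5d were the members that did not pass over the list. Of 17 further probe sets for genes of the list, 15 were negative, with a mean of −0.47. Camera called the list lower (adjusted p = 1.98e-20) and did so with an estimated correlation (adjusted p = 0.0119), the single list of 24 for which that held. The last call held without vehicle array 1 (adjusted p = 0.0460) and was lost without vehicle array 2 or 3 or treated array 1, 2 or 3 (adjusted p between 0.0577 and 0.109), while the mean of the list stayed between −0.49 and −0.54. Without vehicle array 1 the list mean stayed at −0.52. The exact two-sided permutation test of the array means gave p = 0.1, the smallest that 3 against 3 allows.

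**Figure D4:**
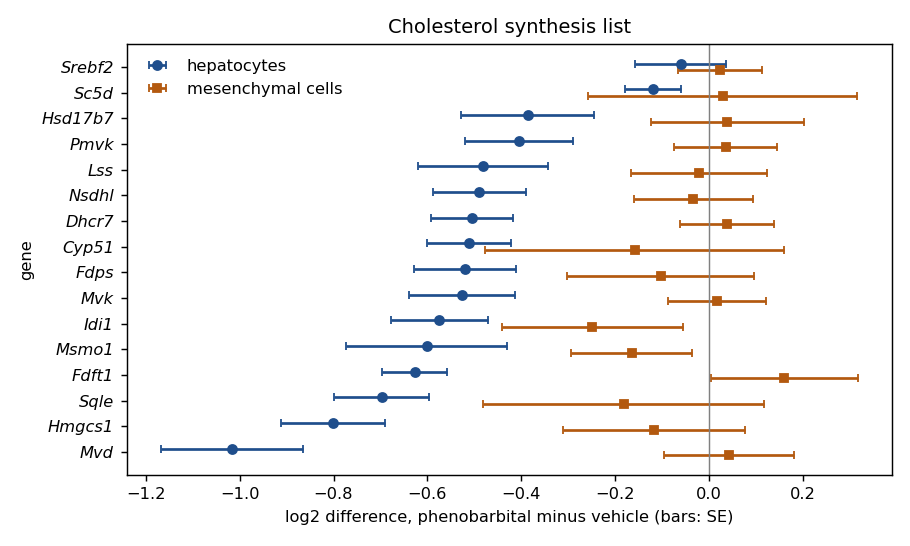
Log2 difference of phenobarbital minus vehicle (horizontal axis, bars: SE) for 16 genes of cholesterol synthesis (vertical axis) in hepatocytes (circles) and mesenchymal cells (squares). All 16 differences are negative in hepatocytes, with a mean of −0.52, and 8 of 16 are negative in mesenchymal cells.

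The other lists called lower in hepatocytes by camera were acute phase, immediate early, unfolded protein response and Wnt and pericentral genes. Their camera adjusted p ranged from 1.39e-06 for the immediate early list to 0.000134 for the Wnt and pericentral list, and no call held with an estimated correlation (adjusted p = 0.418 for each). In acute phase genes, which the liver secretes in inflammation, 14 of 16 members were negative with a mean of −0.77, and serum amyloids had the widest differences (Saa2 −3.02, SE 0.80, and Saa1 −2.34, SE 0.72), though none passed and the list means of single arrays overlapped between the groups. Without treated array 3 both passed over all genes, at −4.08 and −3.32, and 9 members passed over the list alone, as 6 did without vehicle array 3. All 12 immediate early and dissociation stress genes were negative, with a mean of −0.56, and Fos (−0.94, SE 0.24), Egr1 (−0.90, SE 0.26) and Zfp36 (−0.31, SE 0.09) passed over the list alone, but none of these 3 did without vehicle array 1 or 2 or treated array 1 or 2, and 7 members did without vehicle array 3. For the chaperones and unfolded protein response, 18 of 20 were negative with a mean of −0.29, and the members past the list were the asparagine synthetase Asns (−1.21, SE 0.23) and the glutathione-degrading Chac1 (−0.73, SE 0.16), both targets of the transcription factor Atf4 and neither a chaperone. Both were lost without treated array 1 or 2, and Chac1 without vehicle array 1 or 3. All 8 tested Wnt and pericentral genes were negative, with a mean of −0.59, and 4 passed the list: Oat (−1.42, SE 0.41), the glutamate transporter Slc1a2 (−1.10, SE 0.30), glutamine synthetase Glul (−0.77, SE 0.21) and the Wnt inhibitor Notum (−0.72, SE 0.14). Notum alone passed the list without vehicle array 3, Oat was also lost without vehicle array 2, and Glul without treated array 1 or 2. Without treated array 1 the Wnt and pericentral mean was −0.35 and its call was lost (adjusted p = 0.0811). Vehicle array 1 had the highest immediate early list mean of the hepatocyte arrays, 9.36, against 8.96 and 8.73 in the other vehicle arrays. Without it the list mean was −0.40, and that of the unfolded protein response −0.17.

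Of the remaining 15 tested lists none passed camera in hepatocytes, with list means between −0.19 and 0.13. They covered transporters, NRF2 targets, cell cycle, growth arrest, periportal genes, gluconeogenesis, lipogenesis, bile acids, nuclear receptors, cytokines, extracellular matrix and the markers of hepatocytes and of macrophage, endothelial and stellate cells. Single members passed over their own lists. Bcl6 (1.78, SE 0.36) was higher, and Igfbp1 (−1.64, SE 0.25), the DNA damage response gene Gadd45g (−0.99, SE 0.17), Myc (−1.13, SE 0.28) and cyclin D1 (Ccnd1, −0.59, SE 0.12) were lower, as were Btg2, Bcl2l1, Tgfa, Col4a2 and Fn1. With 1 array left out at a time, Bcl6, Igfbp1, Gadd45g, Col4a2 and Fn1 passed over their lists each time, Ccnd1 only without vehicle array 1, Bcl2l1 only without treated array 3 and Tgfa never. Myc was lost without treated array 1 or 2, and Btg2 without vehicle array 1 or 2 or treated array 2 or 3. A further probe set of Fn1 had −0.09 (SE 0.18), and further ones of Tgfa had −0.01 and 0.12. Further probe sets of Bcl6, Btg2, Ccnd1 and Bcl2l1 kept the sign.

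The same comparison in mesenchymal cells called no gene. Of 8003 genes tested none passed in limma (smallest adjusted p = 0.998), and 232 had an unadjusted p under 0.05, where chance gives 400. The groups did not overlap in 616 genes (7.70%, where chance gives 10%). The smallest unadjusted p belonged to the heat shock gene Hspa1a (−1.27, SE 0.24), Stx3 (−0.42, SE 0.08) and Washc4 (−0.42, SE 0.08) among negative differences, and to Pam (0.55, SE 0.10), the chemokine receptor Ackr1 (0.69, SE 0.13) and Sertad1 (0.39, SE 0.08) among positive ones. Cyp2b10 read 9.39, 7.82 and 7.57 in the treated arrays, a mean of 8.26 ± 0.99 (SD, n = 3), against a vehicle mean of 7.26 ± 0.12 (SD, n = 3), and its other 2 probe sets had differences of 2.47 and 2.60. Cyp2c29 had 2.74 (SE 0.71), Meg3 1.12 (SE 0.33), Mki67 0.36 (SE 0.19), Alas1 −0.05 (SE 0.16), Cyp3a11 0.35 (SE 0.71), Gadd45b −0.07 (SE 0.16) and Alb 0.14 (SE 0.34). Meg3 was the 1 tested member of its list, so adjustment over that list left its unadjusted limma p of 0.0133 as it was. Its limma adjusted p over all genes was 0.998. The 4 other probe sets of Meg3 had differences between −0.02 and 0.56. All 15 hepatocyte markers were positive in these arrays, with a mean of 0.41, which differed by less than the spread between arrays (exact two-sided permutation p = 0.6, smallest possible 0.1). The mean was −0.02 without treated array 1, 0.09 without vehicle array 1, 0.61 without vehicle array 2 and 0.65 without treated array 3. In treated array 1 hepatocyte markers stood at a median of 11.9% of their hepatocyte level, against 4.0% to 6.2% in the vehicle arrays.

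As sets, 12 of 27 lists passed camera in mesenchymal cells, 9 higher and 3 lower, and none did with an estimated correlation (lowest adjusted p = 0.648). The lower lists were immediate early genes, with 14 of 15 members negative and a mean of −0.52 (Hspa1a and Hspa1b, −0.85, passed over the list alone), the unfolded protein response, with 16 of 18 negative and a mean of −0.14, and Kupffer and macrophage markers, with 12 of 13 negative and a mean of −0.07. The higher lists included interferon response (13 of 14 positive, mean 0.24, with Bst2 at 0.52 and Cxcl10 at 0.79), cell cycle (15 of 20, mean 0.18), stellate and fibroblast markers (9 of 10, mean 0.27) and extracellular matrix (8 of 12, mean 0.14, with Col3a1 at 0.84). A further probe set of Col3a1 had 0.095 (SE 0.139). The other 5 were lists whose genes are high in hepatocytes: P450 enzymes (mean 0.95), conjugation enzymes (0.30), periportal genes (0.49), lipogenesis (0.31) and the hepatocyte markers themselves. Cholesterol synthesis had 8 of 16 members negative and a mean of −0.04 (camera adjusted p = 0.466), but without treated array 1 its mean was −0.17 and camera called it lower (adjusted p = 0.000262), a call lost with an estimated correlation (adjusted p = 0.796). Without treated array 1, whose hepatocyte markers were high, 5 lists passed, and the means of P450, conjugation, periportal, lipogenesis, cell cycle and macrophage genes were 0.36, 0.02, 0.03, 0.03, 0.05 and 0.01, none past camera, while that of stellate genes was 0.45. Vehicle array 1 had the highest immediate early mean (11.09, against 10.02 and 9.96 in the other vehicle arrays). Without it 3 lists passed, the immediate early (mean −0.23), interferon (0.33) and cell cycle (0.26) lists. The means of conjugation, periportal, lipogenesis, stellate, macrophage and unfolded protein response genes were then 0.15, 0.14, 0.12, 0.10, −0.03 and −0.01, none past camera, and the P450 (0.72) and extracellular matrix (0.10) calls were lost too. The extracellular matrix call was lost as well without treated array 1 (0.18) or 3 (0.13) or vehicle array 2 (0.15), and that of cell cycle without vehicle array 2 (0.10). Without treated array 2 the stellate (0.16) and unfolded protein response (−0.10) calls were lost. The mean of macrophage markers was −0.20 in that fit, −0.13 without vehicle array 3 and −0.02, with the call lost, without treated array 3. The means of conjugation, periportal and lipogenesis genes were 0.48, 0.83 and 0.49 without treated array 3, and that of periportal genes 0.75 without vehicle array 2. The immediate early and interferon lists passed in each fit that left out 1 array. In the list means of single arrays the groups overlapped for 11 of the 12 lists, all but extracellular matrix. With all 12 arrays in 1 fit 18 lists passed, and the macrophage call was lost (adjusted p = 0.0820). The extracellular matrix and stellate calls were lost with the stricter filter on low values (adjusted p = 0.207 and 0.105) and with the mean of all probe sets of a gene (adjusted p = 0.207 and 0.0831), and the conjugation (adjusted p = 0.289) and cell cycle (adjusted p = 0.0672) calls with that filter. With array weights 4 lists passed, the cell cycle (0.26), immediate early (−0.35), interferon (0.30) and macrophage (−0.12) lists. In acute phase genes, which did not pass camera, 11 of 13 members were positive with a mean of 0.25, and without treated array 2 the mean was −0.16. That array had the highest acute phase mean of the mesenchymal arrays, 9.56, against 8.37 and 7.97 in the other treated arrays, and the highest mean of neutrophil markers, 8.12, against 6.01 and 6.31. Without treated array 3 or vehicle array 2 its mean was 0.60 and 0.50 and camera called it higher, a call lost with an estimated correlation (adjusted p = 0.549 and 0.651).

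Whether phenobarbital acted differently on the populations was tested with the difference of the effects, hepatocytes minus mesenchymal cells. No gene of 9031 passed in limma, with 492 genes at an unadjusted p under 0.05 where chance gives 452. Cyp2b10 came nearest, with a difference of effects of 4.51 (SE 0.60) and a limma adjusted p of 0.108. It passed without mesenchymal treated array 1, where hepatocyte markers were high (5.08, limma adjusted p 0.00117), and with array weights (4.82, limma adjusted p 0.0114). Among those with the smallest p were also Ccnd1 (−0.88, SE 0.15), Smox (−1.11, SE 0.21), Mvd (−1.06, SE 0.22), Stx3 (0.78, SE 0.17) and Plekhf2 (0.59, SE 0.13). As sets, 6 of 28 lists passed camera, each with a lower effect in hepatocytes, and with an estimated correlation none did (lowest adjusted p = 0.335). Cholesterol synthesis had 16 of 16 negative differences with a mean of −0.48 (adjusted p = 1.19e-10, and adjusted p = 0.335 with an estimated correlation). Acute phase genes had 15 of 16 with a mean of −0.97 (adjusted p = 0.000833, and adjusted p = 0.832 with an estimated correlation). Both lists had much lower levels in mesenchymal arrays, where hepatocyte RNA was present, so these contrasts do not show how mesenchymal cells themselves responded. The acute phase call was lost with array weights (mean −0.55, adjusted p = 0.360), and the mean was −0.51 (adjusted p = 0.0205) without mesenchymal treated array 2, whose acute phase and neutrophil levels were the highest. The others were Wnt and pericentral genes, hepatocyte markers, bile acid metabolism and extracellular matrix. With the replicate number as a block the extracellular matrix call was lost (adjusted p = 0.0515) and stellate markers, with a mean of −0.30, passed (adjusted p = 0.0210). With array weights the hepatocyte marker mean was 0.06, and the calls of hepatocyte markers and of Wnt (−0.41), bile acid (−0.20) and extracellular matrix (−0.18) genes were lost. The bile acid and extracellular matrix calls were also lost with the stricter filter on low values (adjusted p = 0.0557 and 0.0721) and with the mean of all probe sets of a gene (adjusted p = 0.0535 and 0.231). Without mesenchymal treated array 1 the hepatocyte marker mean was −0.02, and its call and those of bile acid (−0.11) and Wnt (−0.30) genes were lost. Without mesenchymal vehicle array 1 these 3 calls (−0.12, −0.24 and −0.39) and that of extracellular matrix (−0.18) were lost, and without hepatocyte vehicle array 3 the same 4 (−0.43, −0.38, −0.37 and −0.19). Without hepatocyte treated array 2 the hepatocyte marker (−0.43), bile acid (−0.36) and extracellular matrix (−0.13) calls were lost, and without hepatocyte treated array 1 the Wnt (−0.29) and bile acid (−0.31) calls. The bile acid call was also lost without hepatocyte vehicle array 2 (−0.33), and the extracellular matrix call without hepatocyte vehicle array 1 (−0.19) or mesenchymal treated array 3 (−0.20), where the hepatocyte marker mean was −0.69. The number of lists was 2 without hepatocyte vehicle array 3, 3 without hepatocyte treated array 2, and 10 or 11 without mesenchymal vehicle array 2 or 3 or treated array 2 or 3. Without both vehicle arrays numbered 1, 3 lists passed, among them cholesterol synthesis (adjusted p = 1.89e-11) and acute phase (adjusted p = 0.0361), both lost with an estimated correlation (adjusted p = 0.469 and 0.973).

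Across the 7095 genes tested in both populations, the log2 differences of hepatocytes and mesenchymal cells correlated at Pearson r = 0.217 and Spearman rho = 0.0816, and 52.1% of genes had the same sign. Genes are not independent replicates. No control array was shared between the comparisons, but vehicle samples of the same number deviated together in both populations, which gives a positive r with no effect. The covariance of the log2 differences was 0.00715, and the shared deviations of the vehicle samples alone give 0.00353, or an r of 0.108 with the observed spread. The r was 0.133 without mesenchymal treated array 1 and 0.142 without hepatocyte vehicle array 1.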

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

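The tests of the clock genes, of Cyp2b10 in mesenchymal arrays and of vehicle replicate 1 in the cholesterol pattern were chosen after the results were seen. The bounds for array scaling, for single arrays, for a clock difference between the groups and for other splits were written before. The list of clock genes that the clock bound counts was itself added after the values were seen, so that bound was not fully set beforehand. Tests had also been written for the immediate early list, 1 before and 1 after its values were seen, and were set aside for those of the clock genes. Its mean per array over 16 measured genes differed by −0.61 between treated and vehicle mesenchymal arrays, with an SD within groups of 0.47 and groups that overlapped. In hepatocytes it differed by −0.47, with an SD of 0.28. The test written after concerned dissociation differences, and the overlap of the mesenchymal groups met its condition for that explanation.

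The difference of effects between hepatocytes and mesenchymal cells passed camera for 6 lists, which is why they are listed. With an estimated correlation none did (adjusted p = 0.335 for cholesterol synthesis and 0.832 for each of the other 5), and with the replicate number as a block the extracellular matrix call was lost (adjusted p = 0.0515). The mean difference was −0.48 for cholesterol synthesis, −0.97 for acute phase genes, −0.49 for Wnt and pericentral genes, −0.44 for hepatocyte markers, −0.38 for bile acid metabolism and −0.22 for extracellular matrix. In acute phase genes the hepatocyte mean was −0.77 over 16 genes, and the mesenchymal mean was 0.25 over the genes tested there. Over all 16 genes the mesenchymal mean was 0.20. But without mesenchymal treated array 2, where neutrophil markers were also the highest, the mesenchymal mean was −0.16 and the difference −0.51. With array weights the call was lost (−0.55). For hepatocyte markers the means were −0.04 and 0.41, and the difference was −0.02 without mesenchymal treated array 1 and −0.12 without mesenchymal vehicle array 1, with the call lost. Cholesterol synthesis and acute phase were the lists that passed without each single array, and each of the other 4 was lost in at least 4 of the 12 fits that left out 1 array. Of 100 splits of the arrays 85 gave as many lists or more, up to 17, so chance is not excluded as the source of the number, and of the 10 splits that kept the replicate numbers of both populations together 9 did, up to 16. With no gene past the threshold in the difference of effects, all 100 splits gave as many, and the highest other had 2.

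Among the 10 splits of 6 arrays, the real one gave 4 genes in hepatocytes and was 1 of 10 that did, with 0 as the highest other. Lists past camera in hepatocytes numbered 9, and 5 of the 10 splits gave as many, up to 11. In mesenchymal cells 10 of 10 splits gave 0 genes or more, the highest other having 0, and 6 of 10 gave 12 lists or more, up to 20. The difference between populations gave 7470 genes and 1 of 10 splits as many, with 0 as the highest other. These 10 splits are too few for a share under 0.05. The r of 0.217 between the populations was matched in size by 9 of 100 splits, with 0.288 as the highest other, so chance is not excluded. Those splits were drawn separately in each population and leave out that vehicle samples of the same number deviated together, which by itself gives a positive r. In the 10 splits that kept the numbers together, chosen after the results were seen, the other 9 had an r between 0.0989 and 0.201, against the real 0.217, and these are too few for a share under 0.05.

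In vehicle replicate 1 of both populations the clock genes lay apart: their median absolute deviation from the other 2 arrays of the group was 1.30 in hepatocytes and 1.32 in mesenchymal cells, against 0.40 to 0.79 in the other vehicle arrays, whose comparison includes replicate 1, and at most 0.24 in the phenobarbital arrays. All 15 clock genes of that hepatocyte array, and 13 of 15 in the mesenchymal array, moved toward the opposite clock phase, with Dbp 46.1-fold and 39.8-fold lower and Arntl 12.2-fold and 4.86-fold higher, so a different time of tissue collection is a candidate explanation. Dbp in both arrays numbered 1, and Arntl in the other hepatocyte vehicle arrays, lay below the 40th percentile of the array. The Dbp folds and the Arntl fold of 12.2 are therefore rough and may be too small. Npas2 and Bhlhe41 lay below that percentile in each array of both populations, and Nfil3 in each mesenchymal array. The directions of these genes in the counts above are uncertain. Dissociation stress stays open: Per1, also an immediate early gene, differed by −1.30 and −1.32 but is itself a clock gene and decides nothing, and the immediate early list mean of replicate 1 was the highest of the vehicle arrays in both populations (9.36 and 11.09). A treated sample labelled as vehicle is argued against by Cyp2b10, which differed by −5.07 from the lowest treated hepatocyte array; feeding and lighting stay open, and no biological explanation was tested.

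The fall of cholesterol synthesis genes in hepatocytes kept its size without each single array. The value nearest to 0 without 1 array was −0.49. Without vehicle replicate 1, with the median clock gene difference down from 0.62 to 0.09, the mean was −0.52. Under median centring and quantile normalization the value nearest to 0 was −0.52. RMA had already brought the arrays to a common distribution, with hepatocyte medians from 7.19 to 7.21. The scaling test could therefore hardly move the mean and decides nothing. The bound written before for a clock difference between the groups was not decisive, since 2 of 12 tested clock genes, Dbp and Nfil3, differed by at least 1 without overlap. Vehicle array 1 stood apart in both genes. Dbp was 6.21 there, against 11.87 and 11.60 in the other vehicle arrays and 11.89 to 12.15 in treated arrays. Nfil3 was 9.71, against 8.15 in each other vehicle array and 7.45 to 7.73 in treated arrays. The cholesterol synthesis mean of vehicle array 1 was 10.9989, against 11.001 and 10.9897 in the other vehicle arrays. That comparison rests on 1 array and decides nothing alone. A time of day difference that leaves the clock genes alike, and feeding before collection, therefore remain open beside an effect of phenobarbital, which may explain the pattern as a hypothesis.

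Cyp2b10 was higher in the 3 mesenchymal arrays of phenobarbital mice than in the vehicle arrays, without passing. It stood at 6.38%, 2.14% and 1.81% of its hepatocyte level, and above the 95th percentile of 170 hepatocyte genes of similar level in 0 of 3 arrays, which carry-over of hepatocyte RNA as a candidate source needs. Its rise over the vehicle arrays was 4.93%, 0.689% and 0.359% of that level, and in arrays 2 and 3 this was below the ratio of each of the 170 genes. The rise has the vehicle level taken off and the ratios of the 170 genes do not, so that comparison decides nothing about carry-over. Cyp2c29, with 155 hepatocyte probe sets to compare, lay above that percentile in treated array 1 (22.9% against 18.5%) and not in the other 2. Induction in the mesenchymal cells themselves cannot be told apart from carry-over, because the 95% interval of the difference reaches 2.09 and the other 2 probe sets had 2.47 and 2.60, also without passing that percentile in any array.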

How the results depend on the processing

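The fits without the pairs of arrays named below, the hepatocyte marker covariate and the block in the vehicle arrays alone were chosen after seeing the data; the other alternatives were fixed before. The cause of each change was not tested except where the arrays or genes left out show it.

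For hepatocytes, 4 genes became 2 at an adjusted p under 0.01 and 1 with all 12 arrays in 1 fit, and ranged from 1 to 5 without single arrays. Tested one by one, 9 probe sets passed, a count of probe sets and not of genes. Lists numbered 9 and became 1 with an estimated correlation, 1 with directional fry and 5 with mixed fry, and 8 to 11 without single arrays. Fdft1 passed in the fewest settings and was at −0.26 with the mean of its probe sets. Cyp2b10 passed in every alternative run. In mesenchymal cells the gene count was 0 in every alternative. Its 12 lists became 0 with an estimated correlation, 0 with directional and 0 with mixed fry, 4 with array weights, 5 with the hepatocyte marker covariate and 18 with all 12 arrays in 1 fit, ranged from 3 to 17 without single arrays, and were 10 without treated and vehicle array 1 together. In the fit of all 12 arrays Kupffer markers were lost (adjusted p = 0.0820), and transporters, NRF2 targets, growth arrest, bile acid, nuclear receptor, acute phase and T and NK cell lists came past. The difference of effects gave 2 genes with array weights and 0 to 1 without single arrays. Its 6 lists became 0 with an estimated correlation, 0 with directional and 1 with mixed fry, 3 with array weights and 3 without both vehicle arrays numbered 1, and ranged from 2 to 11 without single arrays. The difference between populations gave 12277 probe sets when these were tested one by one, and 7151 to 7467 genes without single arrays. Without single arrays the correlation ranged from 0.133 to 0.239, and the hepatocyte transcripts from −0.017 to 0.65.

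With the replicate number as a block, the counts were 4, 0, 0 and 7449 genes for hepatocytes, mesenchymal cells, the difference of effects and the populations, and 7077 for the populations in the 6 vehicle arrays. Of the 4 hepatocyte genes 2 passed with the block, Cyp2c55 and Fdft1 did not, and Cyp2c54 and Igfbp1 came past, though vehicle and treated samples share only a number. Lists with the block were 9, 16 and 6: hepatocyte calls did not change, growth arrest, acute phase, sinusoidal endothelial and T and NK cell lists came past in mesenchymal cells, and stellate markers replaced extracellular matrix in the difference of effects.

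Direction reversed in mesenchymal lists. With array weights the means were 0.051 for conjugation (camera gave it as lower), −0.14 for periportal genes and −0.097 for hepatocyte markers, and 0.056 for hepatocyte markers in the difference of effects. Without treated array 1 they were 0.024, 0.034 and −0.017, and −0.020 in the difference (camera reversed conjugation and periportal genes while their means stayed positive). Without single arrays the means reached 0.48 for conjugation, 0.83 for periportal genes, 0.49 for lipogenesis, −0.20 for Kupffer markers and −0.69 for hepatocyte markers in the difference. Without treated and vehicle array 1 they were −0.12, −0.32 and −0.34, with lipogenesis at −0.14 and Kupffer markers at 0.051. Of 8295 single gene values under alternatives 8237 stayed on their side of the threshold, 38 were lost and 20 gained, and of 599 list values 432 stayed, 154 were lost and 13 reversed. Of 241 single gene results that did not pass, 49 changed sign under at least 1 alternative, and of 141 that passed 0 did. These counts pool all comparisons. Of the results that passed, 4 were phenobarbital differences in hepatocytes, and the rest were differences between the populations. Among those 4, Cyp2c55, Cyp2c29 and Fdft1 lost their calls in fits without single arrays.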

Other observations

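The genes named here were chosen after their values were seen. Leaving out single hepatocyte arrays brought genes past the limma threshold that had not passed with all 6. Without treated array 3, 5 genes passed, and 4 of them were lower: Moxd1 (−4.34), the serum amyloids Saa2 (−4.08) and Saa1 (−3.32), and Arid5b (−1.19). Without vehicle array 3 Cish, a gene induced by cytokine signalling, passed at −1.70, beside Cyp2b10 and Cyp2c29.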
